A study of Mus musculus with 6 samples.

How the data were processed

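RNA of 6 cultures was measured, 3 plates of the adult-derived line A_212 and 3 of the embryonic-derived line N_46. Per the labels' protocols, plates were grown to 70% confluence in medium with 5% fetal bovine serum, total RNA was isolated on columns, and biotin-labelled cRNA was made from 5 µg of RNA. The series used an Affymetrix mouse array of 22690 probe sets, each of which reads a transcript with several short probes near its 3' end. RMA, which corrects background, quantile-normalises arrays and summarises probes on a log2 scale, is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited log2 values are positive and negative, and the median over the 6 arrays is 0 for all 22690 probe sets within 1e-05, so they were centred per probe set at a step that no source used here describes. The base of the log is not stated either. The largest difference, 7.24 for Sox2, would be 24.1 log2 units if the base were 10, beyond the 16 bits of a scanner, and 10.4 if it were a natural log, which that limit does not exclude. Base 2 was taken because RMA gives it. Quantile normalisation makes arrays alike in distribution, so a difference in total RNA between the lines would not show.

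Probe sets were named from the platform annotation: 20380 had 1 gene, 691 had several, 1555 had none and 64 were controls. Through their gene identifiers, 20351 were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table also gave each gene's chromosome and the order of genes along it, and no coordinates are printed because no probe positions were used. Probe sets with several genes were left out. The 12393 genes tested were the means of all probe sets named for the gene alone (4956 genes had more than 1), and 6282 probe sets of all kinds were of a type that can match several transcripts or genes.

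Choices made before the data were examined were the samples, the tests, the 34 gene lists, the alternatives and the rule for naming genes. The design had assumed values with a level. It had taken the brightest probe set per gene as the main value with the mean as an alternative, and because centred values have no brightness, the mean became the main value. Samples were grouped by the cell line in the labels. Genes were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over 12393 genes, adjusted p under 0.05) on all 6 arrays, and counts were also taken at a log2 difference of at least 1. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over 34 lists), which sets a list against the other genes, and again with a correlation estimated per list. Each list's genes were also adjusted over the list alone. The rule named the 10 genes with the largest difference each way among those past the threshold, with no overlap between the lines and with a symbol that is not a clone or predicted name, up to 2 genes each way per list past the threshold, and, whatever their result, Npy, Agrp, Lepr, Insr and the X-inactivation and Y-linked genes. A condition on brightness in that rule could not be applied. Where a list has many named genes, the text gives some of them. The rule gave 143 genes, of which 69 had several probe sets and 4 had probe sets of both signs (Ncam1, Csf1, Ndn and Lepr).

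Alternatives were arrays set to the same median or 75th percentile, array weights, a replicate block, each array left out in turn, all probe sets one by one, treat against a 2-fold bound, camera with an estimated correlation or on ranks, and fry. Added after the data were seen were plain probe sets alone, robust eBayes without a trend, and each chromosome's median difference taken out. On simulated data with 12393 genes, 3 arrays per line and the measured spread, of which 200 genes were changed, limma recovered 83.6% of genes changed by a log2 difference of 0.5, 98.5% of those changed by 1 and 100% of those changed by 2, with 7 false calls among 195 calls. A list shifted by 0.3 was called at an adjusted p of 6.2e-52, or 0.0047 with an estimated correlation, with 0 other lists called. The simulated genes were independent, whereas the correlation estimated in the measured data reached 0.56 for cholesterol and fatty acid genes. The simulated figures for lists therefore do not carry over to correlated lists. Shifts of chromosomes were tested with 10000 permutations of genes. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.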

Results

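Gene expression was measured in a pair of mouse hypothalamic cell lines, both described as expressing neuropeptide Y (NPY), the peptide of hypothalamic neurons that stimulates feeding. One line, A_212, came from adult hypothalamus and the other, N_46, from embryonic hypothalamus, and both had been immortalised by overexpressing the SV40 T-antigen, a viral protein that inactivates p53 and the retinoblastoma proteins. Each line was grown on 3 plates, and RNA of each plate was hybridised to 1 oligonucleotide array, giving 6 arrays. The deposited log2 values are centred, so that every probe set has a median of 0 over the 6 arrays. They hold differences between arrays and no expression level, so whether a gene was expressed at all in either line cannot be read from them. A log base of 2 was inferred and is not stated in the sources used here, and each fold below rests on it. Differences are given as embryonic-derived minus adult-derived, so a positive value is higher in N_46, with the standard error (SE) of the limma fit over 3 arrays per line. The number of arrays limits the precision. The plates are replicates of 1 line each, so p-values measure the spread between plates, and with 1 line per age, age of origin cannot be told apart from any other difference between these lines.

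The study set the embryonic-derived line against the adult-derived line to find which genes differ between them. Of 12393 genes tested, 4853 (39.2%) differed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 2586 higher in the embryonic-derived line and 2267 higher in the adult-derived line. Differences of at least 2-fold were found for 723 genes (5.83%), of which 275 were higher in the embryonic-derived and 448 (62.0%) in the adult-derived line. The values of the lines did not overlap for 6329 genes (51.1%), where chance gives 10%. The median SD between plates was 0.10 on the log2 scale in the adult-derived line and 0.08 in the embryonic-derived line. The majority among all 4853 calls was narrow and turned with the scaling, from 53.3% higher in the embryonic-derived line to 46.9% when each array was set to the same median. Across genes, which are not independent replicates, arrays of a line correlated with r between 0.80 and 0.86 in the adult-derived line and, in the embryonic-derived line, at 0.92 for replicates 2 and 3 and at 0.82 and 0.83 for replicate 1 with them, and arrays of different lines with r between -0.85 and -0.89, a negative value that the centring produces. As a sign of RNA quality, the 3' minus 5' difference of the control probe sets differed between the lines by -0.0010 for Gapdh and by 0.012 for Actb, on the log2 scale. Centring removed the 3' to 5' ratio itself, so these values compare the lines and do not show whether the RNA was sound. The 45 bacterial control probe sets had a median difference of 0.05, with a range from -0.11 to 0.24.

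The largest difference in favour of the embryonic-derived line was that of Sox2, the transcription factor of neural stem and progenitor cells, at 7.24 ± 0.09 (SE, n = 3 arrays per line), a 151-fold difference. It was followed by the carboxylesterase gene Ces1g (6.65 ± 0.13, 100.4-fold), the interferon-inducible Ifi202b (5.76 ± 0.16), Perp, a p53 target that encodes a desmosomal protein (5.41 ± 0.09), and the secreted Wnt modulator Sfrp2 (5.18 ± 0.26). Next came the amino acid transporter Slc6a15 (4.59 ± 0.14), the imprinted gene Mest (4.45 ± 0.23), Epb41l4a (4.18 ± 0.07), the Y-linked Eif2s3y (4.12 ± 0.24) and Penk, which encodes proenkephalin (4.07 ± 0.15). In the other direction, the largest difference was that of Cdh11, a mesenchymal cadherin, at -5.74 ± 0.14, a 53.3-fold difference. The matrix metalloproteinase Mmp2 (-5.26 ± 0.08), thrombospondin 2 (Thbs2, -5.25 ± 0.12) and periostin (Postn, -5.14 ± 0.24) followed, and then the small heat shock protein Hspb1 (-4.81 ± 0.08) and thrombomodulin (Thbd, -4.80 ± 0.13). The glutamate transporter Slc1a6 (-4.74 ± 0.11), the basement membrane gene nidogen 1 (Nid1, -4.63 ± 0.12), the neural crest transcription factor Tfap2b (-4.59 ± 0.10) and Cd99 (-4.53 ± 0.12) completed the 10. Adjusted p-values of these 20 genes in limma ranged from 8.4e-12 for Sox2 to 3.2e-07 for Eif2s3y. The 2 probe sets of Nid1 differed in size, at -6.60 and -2.65, and near-identical family members, as in the families of Ces1g and Ifi202b, may share probe sets.

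**Figure D1:**
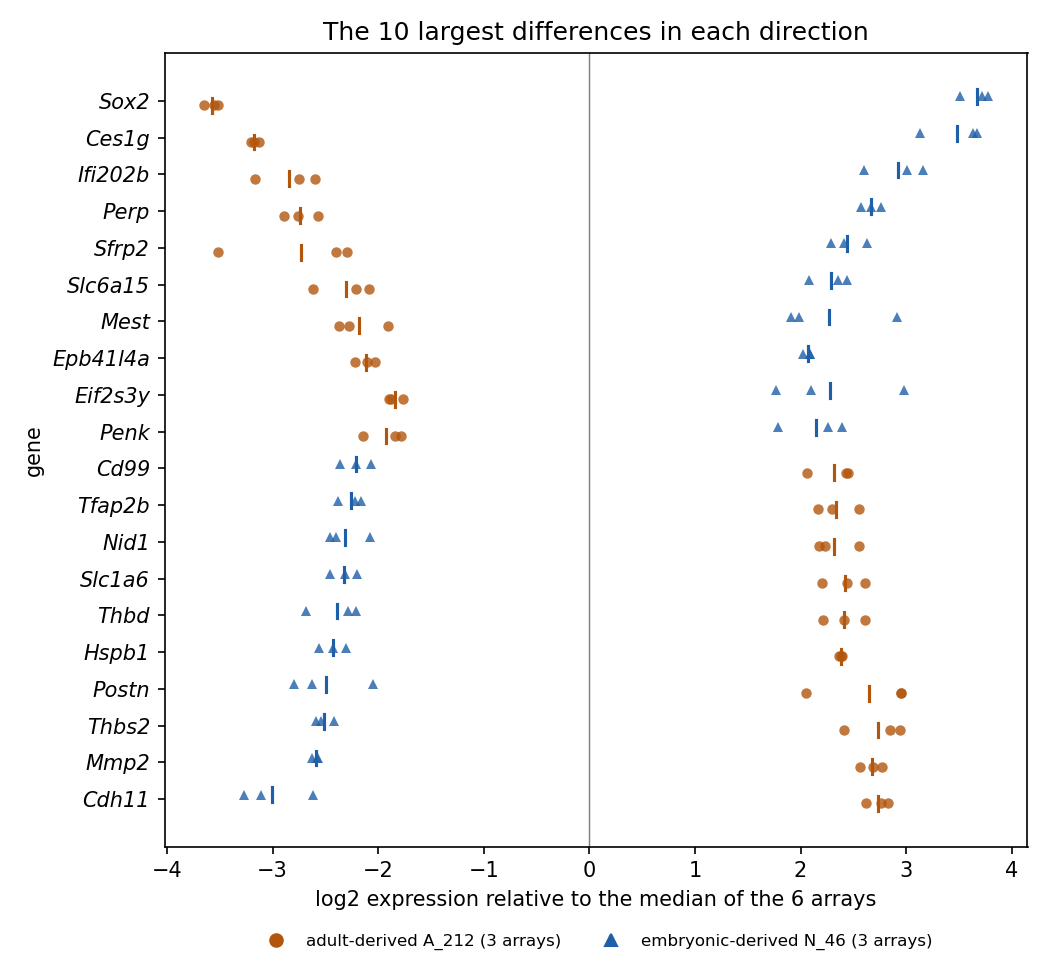
Log2 expression relative to the median of the 6 arrays (horizontal axis) for the 10 genes with the largest difference in each direction (vertical axis), with 1 symbol per array, circles for the adult-derived and triangles for the embryonic-derived line, and short bars at the line means. The arrays of the lines lie on opposite sides of 0 for each of these genes, from Sox2 (7.24) at the top to Cdh11 (-5.74) at the bottom. The choice of genes without overlap and the centring largely bring this about.

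Npy itself, the gene both lines are described as expressing, differed by 0.05 ± 0.08 (95% interval -0.14 to 0.24, limma adjusted p = 0.66). The leptin receptor Lepr differed by 0.01 ± 0.08 (-0.16 to 0.18, adjusted p = 0.93) and the insulin receptor Insr by 0.08 ± 0.09 (-0.11 to 0.27, adjusted p = 0.50), and Agrp was not analysed here because no probe set was named for it alone. Of 26 hypothalamic neuropeptide genes measured, 4 were higher in the embryonic-derived line, 2 were higher in the adult-derived line and 20 did not pass the test, with the same 4 and 2 when adjusted over the list alone. Penk (4.07) and nucleobindin 2 (Nucb2, 0.99), the precursor of nesfatin, were higher in the embryonic-derived line, and Tac1 (-0.61) and Vip (-0.49) were higher in the adult-derived line. Among 34 receptors for hormones and neuropeptides of energy balance, 5 were higher in the embryonic-derived line, 7 in the adult-derived line and 22 did not pass, with 5 and 7 adjusted over the list alone. The NPY receptor gene Npy1r (1.16, with probe sets at 0.34 and 1.97) and the oestrogen receptor gene Esr2 (0.51) had positive differences, and the growth hormone receptor Ghr (-1.93) and the cytokine co-receptor Il6st (-1.82) had negative ones. The 39 insulin and leptin signalling genes divided evenly, with 11 higher in each line and 17 not past the test, or 12 in each line adjusted over the list alone. Irs2, an adaptor of the insulin receptor (1.71), and the Akt inhibitor Trib3 (1.55) were higher in the embryonic-derived line, and Grb10, an adaptor that dampens insulin receptor signalling (-4.46), in the adult-derived line. None of these 3 lists passed camera, with adjusted p-values of 0.59 for neuropeptides, 0.77 for receptors and 0.87 for insulin and leptin signalling.

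Neuronal genes differed in both directions. Of 33 genes of the neuronal cytoskeleton and identity, 10 were higher in the adult-derived line, 4 in the embryonic-derived line and 19 did not pass, with the same 10 and 4 adjusted over the list alone. The neuronal surface glycoprotein Thy1 (-3.41), which fibroblasts also carry, and the growth-associated microtubule regulator Stmn2 (-3.09) were higher in the adult-derived line, and the kinesin heavy chain gene Kif5c (1.04) in the embryonic-derived line. Ncam1 was called at 0.39, but its 6 probe sets went both ways and the call ended when plain probe sets alone were used (0.13, adjusted p = 0.23). On the same arrays, fibroblast and mesenchymal markers had a median difference of -0.57. The neuronal list as a whole did not pass (camera adjusted p = 0.095), and it passed without embryonic replicate 3 (0.046). With an estimated correlation on all arrays its camera adjusted p was 0.76. Of 30 genes of synaptic vesicles and regulated secretion, 4 were higher in the embryonic-derived line, 6 in the adult-derived line and 20 did not pass, with 3 and 6 adjusted over the list alone. The chaperone gene Scg5 (0.44) and Cplx2 (0.40) stood on one side, and the peptide-amidating enzyme gene Pam (-1.22) and the synaptotagmin gene Syt4 (-0.97) on the other. Among 22 genes of GABA and glutamate transmission, 3 were higher in the embryonic-derived line, 4 in the adult-derived line and 15 did not pass, and among 27 voltage-gated ion channel genes 3, 7 and 17, with the same calls adjusted over the list alone. The postsynaptic scaffold gene Homer1 (0.44) and the channel gene Hcn2 (0.44) were higher in the embryonic-derived line, and gephyrin (Gphn, -0.51), the GABA receptor subunit gene Gabrb1 (-0.46) and the calcium channel genes Cacna1c (-0.98) and Cacna1a (-0.59) in the adult-derived line. These 3 lists did not pass (camera adjusted p = 0.73, 0.92 and 0.92).

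Some developmental regulators differed between the lines, as did 39.2% of all genes tested. Of 38 hypothalamic developmental transcription factors, 10 were higher in the embryonic-derived line, 4 in the adult-derived line and 24 did not pass, with the same calls adjusted over the list alone. Lhx2, a LIM-homeobox gene of early forebrain development (95% interval 3.71 to 4.29), and the POU-domain gene Pou3f3 (3.47) were higher in the embryonic-derived line, and Lhx6 (-0.87) and Dlx1 (-0.51), both genes of GABAergic lineages, in the adult-derived line. Of 37 neural progenitor markers, 15 were higher in the embryonic-derived line, 7 in the adult-derived line and 15 did not pass, with 16 and 8 adjusted over the list alone. Sox2 (7.24) and the inhibitor of differentiation Id4 (2.93) led one side, and Sox4 (-1.10) and Zbtb20 (-0.92) the other. Of 31 Hox genes, which pattern the body axis behind the forebrain, 8 were higher in the embryonic-derived line, 0 in the adult-derived line and 23 did not pass, with 7 and 0 adjusted over the list alone. Hoxa5 differed by 2.22 and Hoxa9 by 2.05, the latter with probe sets at 0.38 and 3.72. None of the 3 lists passed camera, with adjusted p = 0.095 for the developmental factors, 0.17 for progenitor markers and 0.099 for Hox genes. Without adult replicate 3, the developmental factors (0.025) and the Hox genes (0.040) passed, and the Hox genes also passed with each chromosome's median difference taken out (0.044), a setting added after the data were seen. In camera with an estimated correlation on all 6 arrays, the adjusted p was 0.92 for the developmental factors and 0.86 for the Hox genes.

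Markers of other neural cell types went both ways. Of 20 astrocyte markers, 2 were higher in the embryonic-derived line, 7 in the adult-derived line and 11 did not pass. The glutamate transporter gene Slc1a3 (2.47) and the connexin gene Gja1 (1.30) were higher in the embryonic-derived line, and Apoe (-1.17) and Clu (-1.02) in the adult-derived line. Among 15 oligodendrocyte lineage markers, 2 were higher in the embryonic-derived line, 4 in the adult-derived line and 9 did not pass, led by the growth factor receptor gene Pdgfra (-3.00), also a mesenchymal gene, and the proteoglycan gene Cspg4 (-1.31). Among 18 tanycyte and ependymal markers, the counts were 1, 6 and 11, with Lhx2 higher in the embryonic-derived line, as above, against adrenomedullin (Adm, -2.68) and versican (Vcan, -2.53). Among 19 Schwann cell and neural crest markers, 3 were higher in each line and 13 did not pass, with Tfap2a (1.66) and Egr2 (0.53) against Tfap2b (-4.59) and Gata3 (-0.99). Among 19 microglia and macrophage markers, 2 were higher in each line and 15 did not pass, with Tmem119 (-3.26) and Cd14 (-0.57) higher in the adult-derived line. For each of these 5 lists the count adjusted over the list alone was the same, and camera adjusted p-values were 0.68, 0.59, 0.33, 0.92 and 0.92.

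Many mesenchymal marker and matrix genes were higher in the adult-derived line. Of 34 fibroblast and mesenchymal markers, 21 were higher in the adult-derived line, 3 in the embryonic-derived line and 10 did not pass, with 21 and 4 adjusted over the list alone, and the median difference was -0.57. Besides Mmp2 (-5.26) and Thbs2 (-5.25), Postn (-5.14) belonged to the genes higher in the adult-derived line, whereas the collagen gene Col1a1 (0.55) and Twist2 (0.39) were higher in the embryonic-derived line. The camera adjusted p was 1.7e-08, and the adjusted p = 0.46 with an estimated correlation. Of 20 smooth muscle and pericyte markers, 14 were higher in the adult-derived line, 1 in the embryonic-derived line and 5 did not pass, with the same calls adjusted over the list alone and a median of -0.41. The smooth muscle actin gene Actg2 (-4.17) and calponin 1 (Cnn1, -2.65) were higher in the adult-derived line and the adhesion molecule gene Mcam (0.73) in the embryonic-derived line, with a camera adjusted p of 2.5e-05 and an adjusted p = 0.46 with an estimated correlation. Of 40 collagen, laminin and other matrix genes, 23 were higher in the adult-derived line, 4 in the embryonic-derived line and 13 did not pass, with 23 and 5 adjusted over the list alone and a median of -0.40. Nid1 (-4.63) and asporin (Aspn, -4.02) were higher in the adult-derived line and nidogen 2 (Nid2, 1.75) in the embryonic-derived line, with a camera adjusted p of 1.0e-05 and an adjusted p = 0.46 with an estimated correlation. These 3 lists shared 0 genes. Adult replicate 1 lay -0.11 from its line mean on average over the fibroblast list and -0.12 over the matrix list, and embryonic replicate 1 lay 0.11 and 0.08 from its own, and the 3 lists passed camera without either array. Among the 9 splits of the 6 arrays that mix the lines, 4 also called the fibroblast list, 6 the smooth muscle list and 5 the matrix list. Such splits keep part of the difference between the lines, so their calls are no measure of chance. Endothelial markers (5 higher in the embryonic-derived line, 3 in the adult-derived line, 11 of 19 not past the test) and epithelial markers (2, 1 and 17 of 20) did not pass camera (both adjusted p = 0.92), with the same calls adjusted over each list alone. Plvap (1.46), Flt4 (0.72) and the desmosomal gene Dsp (0.77) were higher in the embryonic-derived line, and endoglin (Eng, -2.44), Flt1 (-0.92) and Krt19 (-1.01) in the adult-derived line.

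Most interferon-stimulated genes measured were higher in the adult-derived line. Of 32 measured, 25 were higher in the adult-derived line, 1 in the embryonic-derived line and 6 did not pass, with the same 25 and 1 adjusted over the list alone, and the median difference was -0.90. The antiviral genes Ifit1 (-3.30) and Ifi35 (-3.06) had the largest differences, and the 1 gene higher in the embryonic-derived line, Ifit2 (0.28), lost its call in several settings. The camera adjusted p was 3.6e-11, and the adjusted p = 0.46 with an estimated correlation. Of the 9 splits that mix the lines, 7 also called this list, but they keep part of the difference between the lines and are no measure of chance. Adult replicate 1 lay -0.20 from its line mean on average over the list, and leaving out 1 array gave camera adjusted p-values from 2.9e-14 without that replicate to 1.2e-08 without adult replicate 3. Of 23 genes of MHC class I and antigen presentation, 13 were higher in the adult-derived line, 1 in the embryonic-derived line and 9 did not pass, with the same calls adjusted over the list alone and a median of -0.30. The immunoproteasome gene Psmb8 (-1.15) and the peptide transporter gene Tap2 (-1.05) were among the 13, and H2-Ke6 (0.32), an enzyme gene that lies in the MHC region and does not present antigen, was the exception. This list passed camera at an adjusted p of 0.0018, and its adjusted p = 0.76 with an estimated correlation, with 3 of the 9 mixed splits calling it too. Of 43 cytokine, chemokine and NF-kB genes, 7 were higher in the embryonic-derived line, 11 in the adult-derived line and 25 did not pass, adjusted over the list alone as well, and the list did not pass camera (adjusted p = 0.17). Il33 (1.61) was higher in the embryonic-derived line, and Il15 (-2.17) and the adhesion molecule gene Icam1 (-1.91) in the adult-derived line.

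Secreted signals and imprinted genes held large differences in both directions. Of 46 Wnt signalling genes, 11 were higher in each line and 24 did not pass, with 11 and 12 adjusted over the list alone, and the largest were those of the modulators Sfrp2 (5.18) and Sfrp1 (2.49) on one side and Rspo2 (-4.02) and Dkk3 (-2.38) on the other. The 4 probe sets of Sfrp1 ran from 0.40 to 3.58. Of 43 TGF-beta and BMP signalling genes, 11 were higher in the embryonic-derived line, 7 in the adult-derived line and 25 did not pass, with 13 and 8 adjusted over the list alone. The matricellular gene Ccn2 (2.93) and the activin subunit gene Inhbb (1.38, with probe sets at 0.24 and 2.52) were higher in the embryonic-derived line, and Ltbp2 (-3.71) and Tgfbi (-3.16) in the adult-derived line. Of 28 imprinted genes, 11 were higher in the adult-derived line, 4 in the embryonic-derived line and 13 did not pass, with the same calls adjusted over the list alone. Mest (4.45) and Asb4 (0.88) stood against Grb10 (-4.46) and Ndn (-2.12). The 8 probe sets of Ndn ran from -4.48 to 0.09 and the 3 of Grb10 from -6.44 to -2.79. Camera adjusted p-values were 0.96, 0.92 and 0.12. The imprinted list passed (0.042) with each chromosome's median difference taken out, a setting added after the data were seen. With an estimated correlation in the main fit its camera adjusted p was 0.82.

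Genes that mark the sex chromosomes set the lines apart. Xist, the RNA that coats the inactive X chromosome, was higher in the adult-derived line (-3.62 ± 0.09), whereas the Y-linked Eif2s3y (4.12 ± 0.24), Uty (2.53 ± 0.09) and Kdm5d (1.24 ± 0.09) were higher in the embryonic-derived line, with no overlap between the lines over the 6 arrays. The 3 probe sets of Kdm5d differed in size, at 2.93, 0.64 and 0.15, and the 3 of Xist ran from -5.44 to -2.43. Of the X-linked partners of these genes, Kdm6a was higher in the adult-derived line (-0.88 ± 0.09) and so was Eif2s3x (-0.36 ± 0.08), the latter not with plain probe sets alone (-0.27, adjusted p = 0.087). Kdm5c (0.15 ± 0.09), Ddx3x (0.09 ± 0.12) and the antisense gene Tsix (0.02 ± 0.10) did not pass. Of these 9 genes, 3 were thus higher in each line and 3 did not pass, adjusted over the list alone as well, with a camera adjusted p of 0.92.

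Among metabolic and clock lists, 1 of 3 passed camera. Of 32 genes of cholesterol and fatty acid synthesis and use, 10 were higher in the adult-derived line, 3 in the embryonic-derived line and 19 did not pass, with the same calls adjusted over the list alone and a median of -0.22. The cholesterol transfer gene Stard4 (-0.80) and the sterol desaturase gene Sc5d (-0.72) were higher in the adult-derived line, and Pparg (1.82) and Cpt1a (0.66), which act in fat storage and fatty acid oxidation, in the embryonic-derived line. The camera adjusted p of 0.027 did not hold with array weights (0.15), without adult replicate 2 (0.062) or without embryonic replicate 1 (0.24), and the adjusted p = 0.96 with an estimated correlation. Of the 9 mixed splits, which keep part of the difference between the lines, 7 called this list. Of 20 circadian clock genes, 11 were higher in the embryonic-derived line, 3 in the adult-derived line and 6 did not pass, with 11 and 4 adjusted over the list alone, among them Cry1 (0.91) and Rorb (0.90) against Rora (-0.84) and Cry2 (-0.35). Of 30 glycolysis and hypoxia genes, 11 were higher in the embryonic-derived line, 4 in the adult-derived line and 15 did not pass, with 12 and 5 adjusted over the list alone, among them hexokinase 1 (Hk1, 1.01) and Vegfa (0.81) against Adm (-2.68). Neither list passed camera (adjusted p = 0.19 and 0.33).

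Cell cycle, stress and reference lists did not pass camera. Of 43 cell cycle genes, 10 were higher in the embryonic-derived line, 7 in the adult-derived line and 26 did not pass, led by cyclin E1 (Ccne1, 0.78) and Cdk1 (0.55) against Cdc25c (-0.74) and Kif20a (-0.59). Of 25 p53 targets, 7 were higher in the embryonic-derived line, 8 in the adult-derived line and 10 did not pass, with 7 and 9 adjusted over the list alone. Perp (5.41) and the apoptosis gene Pmaip1 (2.40) stood against the cell cycle inhibitor Cdkn1a (-1.47) and Trp53inp1 (-1.47). Of 29 genes of the unfolded protein response, 9 were higher in the embryonic-derived line, 5 in the adult-derived line and 15 did not pass, with Trib3 (1.55) and Chac1 (1.33) against Dnajc3 (-0.42). Of 16 reference transcripts, 4 were higher in the embryonic-derived line, 2 in the adult-derived line and 10 did not pass, and Tfrc (1.61), the transferrin receptor, and B2m (-0.62), the light chain of MHC class I, had the largest differences. For cell cycle, unfolded protein response and reference genes the counts adjusted over the list alone were the same, and camera adjusted p-values of these 4 lists were 0.92, 0.68, 0.92 and 0.92.

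In all, 6 of the 34 lists passed camera with the preset correlation and 0 with an estimated one, where 3 lists (fibroblast, smooth muscle and matrix) had an unadjusted p under 0.05. The estimated correlation rests on only 6 arrays, so missing the threshold there does not show that a list is without a difference. In the 6 lists the median, the mean and the test had the same sign, whereas in 13 of the other 28 they did not. The 137 called genes among the 143 chosen for naming had no overlap between the lines, and their adjusted p-values reached 0.044. SEs of the 143 genes ranged from 0.07 to 0.26 on the log2 scale.

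**Figure D2:**
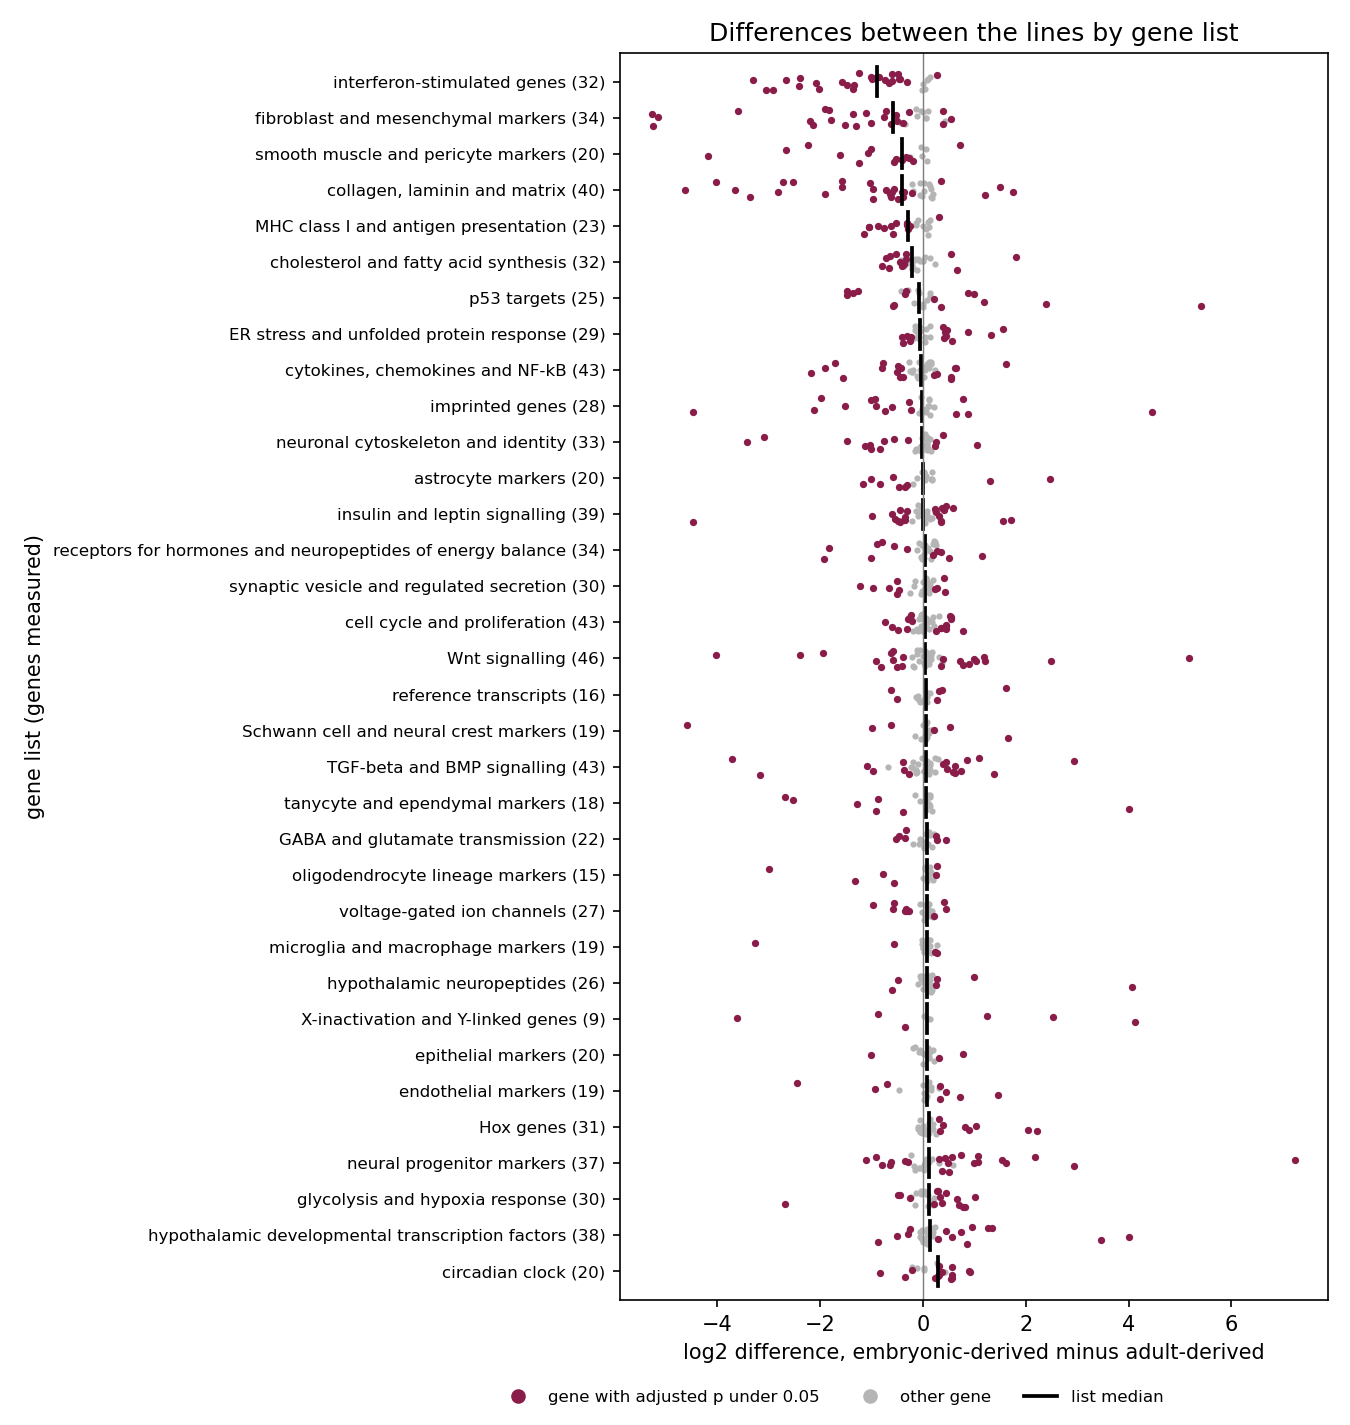
Log2 difference, embryonic-derived minus adult-derived (horizontal axis), of each measured gene of the 34 lists (vertical axis, with the number of genes measured), with dark points for genes at an adjusted p under 0.05, grey points for other genes and a black bar at each list's median. The lowest medians are those of interferon-stimulated genes (-0.90), fibroblast and mesenchymal markers (-0.57) and smooth muscle and pericyte markers (-0.41), and the highest is that of circadian clock genes (0.30).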

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

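Plain probe sets alone, robust eBayes without a trend and chromosome medians taken out were chosen after the data were seen, and the other settings before. Counts of genes stayed within 1.5 times the reported ones in all settings that tested the same genes with the same threshold. Leaving out 1 array gave 1986 to 2858 genes higher in the embryonic-derived and 1891 to 2266 in the adult-derived line, 265 to 284 and 417 to 464 at 2-fold, and 5 to 8 lists. Probe sets tested one by one gave 4003 and 3621, and 477 and 740 at 2-fold, since more features were tested. The stricter treat test against a 2-fold bound gave 138 and 268. Of the 34 lists, 6 passed camera, 0 with an estimated correlation and 17 in fry, which does not compare a list with other genes. With an estimated correlation the adjusted p was 0.46 for the fibroblast, smooth muscle, matrix and interferon lists, 0.76 for MHC class I and 0.96 for cholesterol and fatty acid genes. That last list also missed the threshold with array weights (0.15) and in fry (0.30), and leaving out 1 array gave 0.0025 to 0.24 (0.062 without adult replicate 2 and 0.24 without embryonic replicate 1), and the cause was not tested. Of the 143 named genes, none of the 137 that were called reversed. Reversal was not scored for genes that were not called, and Lepr, 1 of them, went from 0.01 to -0.03 with each array at the same median. A call ended in at least 1 setting for Ugt8a, Ifit2, Grik5, Nkx6-2, Tjp3, Cd68, Trem2, Dnajb9, Ncam1 and Eif2s3x. Over the 143 genes this happened 38 times, against 1821 in which the side of the threshold held. The labels number plates 1 to 3 in each line, and deviations of same-numbered arrays from their line means correlated at -0.03, -0.01 and 0.09, so the numbers were not taken to pair plates; not every array correlated best with its own number. A replicate block gave 2576 and 2258 genes and 6 lists. The dim-gene filter, cyclic loess and the eBayes trend were not run because centred values hold no level, and a floor before log2 did not apply. For the same reason signal over background is unknown.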

Other observations

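The tests on the lists in this paragraph, on immune cells, on parts of chromosomes, on copy number and on sex, and the count of splits for all called genes, were chosen only after the results were seen, as were the genes named here. Ribosome biogenesis genes, which build ribosomal subunits in the nucleolus, were higher in the embryonic-derived line: 36 of 52 measured were higher there, 1 in the adult-derived line and 15 did not pass, with a median of 0.47 (camera p = 1.4e-11, and p = 0.13 with an estimated correlation). Myc, a transcription factor that drives such genes and is itself on the list, differed by 1.72 ± 0.12, and Rrs1 (1.29), Gnl3 (1.15) and Nop2 (1.02) were among the others. Of 6 Iroquois homeobox genes, which pattern the neural tube, 4 were higher in the embryonic-derived line and 0 in the adult-derived line, with Irx3 at 3.62 ± 0.12 and Irx2 at 1.56 ± 0.09 (camera p = 0.0012, and p = 0.10 with an estimated correlation). Of 17 cathepsin genes, lysosomal proteases for the most part, 7 were higher in the adult-derived line, 3 in the embryonic-derived line and 7 did not pass, with Ctsh at -2.29 and Ctsc at -1.60. The median of the list was only -0.014 (camera p = 0.035, and p = 0.097 with an estimated correlation). The 18 glutathione transferase genes did not pass (camera p = 0.91, and p = 0.92 with an estimated correlation), with 5 higher in each line. Of 22 protocadherin beta genes, adhesion molecules encoded in a cluster on chromosome 18, 9 were higher in the adult-derived line and 0 in the embryonic-derived line, with Pcdhb17 at -3.28 and a median of -0.11 (camera p = 6.3e-05, and p = 0.053 with an estimated correlation). With chromosome medians taken out, the median of the list turned to 0.087 (camera p = 0.089 with the preset correlation, and not tested with an estimated correlation). Within the interferon-inducible Ifi200 family the lines went both ways, with Ifi202b (5.76 ± 0.16) and Ifi204 (2.30 ± 0.17) higher in the embryonic-derived line and Mndal (-3.94 ± 0.15) in the adult-derived line, in a family whose members are similar enough to share probes.

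The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4853 genes and 723 at 2-fold, and the highest of the other splits called 0 and 0, so that 1 of the 10 splits reached each real count. In a mixed split the difference between the lines enters the spread within groups, so genes that differ by line are hardly called there. The 0 calls therefore say nothing on chance. For the lists the real split gave 6 and the highest other split 9, and 7 of the 10 splits gave at least 6. The lowest adjusted p among the 9 mixed splits, which keep part of the difference between the lines, was 3.2e-08 for interferon-stimulated genes and 3.6e-07 for fibroblast markers, against 3.6e-11 and 1.7e-08 in the real split. For the smooth muscle, matrix, MHC class I and cholesterol lists at least 1 mixed split gave an adjusted p as low as the real one.

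Most interferon-stimulated genes, 25 of 32, were higher in the adult-derived line, with a list median of -0.90. The list did not pass camera with an estimated correlation (adjusted p = 0.46). Immune cells among the adult-derived cells would raise the microglia and macrophage markers together, and the 19 measured had a median of 0.084 with quartiles at 0.00061 and 0.15, which argues against such cells as the whole source, although Tmem119 (-3.26) and Cd14 (-0.57) were higher in the adult-derived line. Chromosome-wide shifts between the lines were too small to be the main source of this difference, the largest being -0.19 for chromosome 18. With chromosome medians taken out the list median was -0.85, and shifts of that size could not have ended the difference. Age of the source tissue cannot be told apart from the clone with 1 line per age, and a lasting interferon response in line A_212 alone, set off by its immortalisation or culture, may give the same values and was not tested.

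Genes of a chromosome tended to shift together, by little: 12 of 20 chromosomes had a median difference apart from that of all genes (permutation adjusted p under 0.05, with genes taken as independent, which neighbours are not), 6 up and 6 down, the largest downward being -0.19 for chromosome 18 and -0.13 for chromosome 9 and the largest upward 0.13 for chromosome 10 (embryonic minus adult), against at most 0.099 in the other splits of the arrays. Those splits mix the lines and keep only part of the difference between them, so the 0.099 is no measure of chance. The values argue against 1 array out of line as its source in chromosomes 10 and 18, since the smaller of the shifts of chromosomes 10 and 18 stayed at 0.11 or more with any array left out. Neighbouring co-regulated genes in one part of the chromosome are argued against for chromosome 10, whose less shifted part was still at 0.11 (95% bootstrap interval 0.071 to 0.15), but not settled for chromosome 18, where one part shifted by -0.34 and the other by -0.071 (-0.15 to -0.029). Without its 24 measured protocadherin genes, chromosome 18 still shifted by -0.19 (-0.30 to -0.10), which argues against those genes alone as the source of its shift. A different chromosome copy number in the 2 lines is a candidate explanation that stays open. Both parts had the same sign in all 12 chromosomes. Their sizes were alike in some, such as chromosome 9 (-0.13 and -0.14), 5 (0.048 and 0.053), 17 (-0.10 and -0.074) and X (-0.057 and -0.074). In chromosome 2 they were at -0.12 and -0.0066 and in chromosome 19 at 0.058 and 0.010, and no DNA was measured. The shifts are well below the 0.58 that a step from 2 to 3 copies would give if every gene followed dose. They are medians over all genes, and which of these were expressed is unknown, so that size does not count against copy number.

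Xist and the Y-linked genes differed in opposite directions between the lines. Source animals of different sex, female for A_212 and male for N_46, may account for it. The X-linked partners that escape X inactivation were the test, and they leave it open: the 4 genes had a median of -0.13, with Kdm6a and Eif2s3x higher in the adult-derived line and Kdm5c and Ddx3x not past the threshold. Loss of a Y chromosome or a change of X inactivation in culture was not tested, and sex, like age, comes with the line.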
